A study of Homo sapiens with 13 samples.

How the data were processed

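Total RNA of HME1-E6 cells was prepared with an RNeasy kit and libraries with a NEBNext Ultra RNA kit, per the labels' protocols. HME-1 is a non-transformed human mammary epithelial cell line, here with the E6 protein of human papillomavirus. The series holds 13 libraries, 12 of clones obtained after repeated transduction with a cyclin E construct and 1 of the parental line. Groups were taken from the labels. The transduction protocol is attached to all 13 libraries, and HME1-E6 was taken as the untransduced line from its title and characteristics. The 12 clones were treated as separate samples of 1 group. The labels do not say how the cultures were replicated, so p-values measure only the spread between these samples. The lone parental library was assumed to vary like the clones in every model.

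The authors deposited 1 table of TPM values with 194993 transcripts and 55475 gene symbols, in which each library sums to 1000000 TPM. The submitters' processing notes name STAR 2.6.1, Salmon 0.13.1 and the build GRCh37, without their roles. The annotation release and any filter are not given in the sources used here. TPM keeps no depth, so the sequencing depth and the counting error of each value are unknown. A total of 58.2% of transcript values were 0. Because a 0 can be a failed estimate, genes at 0 are said to be listed at 0. TPM is also relative: a few abundant genes can move all others, and ribosomal protein genes took between 13.5% and 21.2% of TPM per library. Salmon can divide reads between near-identical copies, so values of paralogs, pseudogenes, small RNA copies and overlapping genes are uncertain. Whether strand was used is not given in the sources used here. A total of 26 symbols were plain numbers, the trace of spreadsheet date conversion, and were not named.

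Transcript TPM values were summed by gene symbol and analysed as log2(TPM + 1), so fold changes are on that scale and understate changes of low genes. Chromosome, arm, gene order, gene type and GC content were taken from GENCODE 29, matched by transcript identifier (92.8% of transcripts). That release uses another build than the one named by the submitters. It served for these properties alone, and no coordinates are printed. Arms were divided at approximate centromere positions.

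Clones and parental library were compared with limma 3.58.1 in R 4.3.3 (linear model with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Genes entered where the mean of the clone mean and the parental value was at least 1 TPM, which left 14893. Tests on 26 gene lists used camera with a preset correlation of 0.01, with an estimated correlation beside it. The lists covered E2F and S phase, G2/M and mitosis, the cyclin E and CDK2 module, replication stress and DNA damage response, histones, p53 targets, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, hypoxia and glycolysis, cholesterol synthesis, proteasome, heat shock, unfolded protein response, interferon response, NF-kB and secretory cytokines, genes gained or lost in breast cancer, common fragile sites, and markers of basal, luminal, keratinocyte, mesenchymal, fibroblast, endothelial and immune cells. A list needed 5 measured members, which 24 had.

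For each clone the shift of an arm was the median over its genes of log2 clone minus parental library, minus the clone's genome-wide median. It used genes of at least 5 TPM and arms of at least 30 such genes. An arm was called shifted at 0.3 or more in size and outside all 10000 random gene lists of the same size matched on mean expression. Blocks of 50 neighbouring genes were treated alike, with a threshold of 0.4. The same shift against the median of the other 11 clones was computed beside it, because all clones share the parental library. Relations across clones used Pearson and Spearman correlation with 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

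The designs, gene lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule took CCNE1 first. It then took the 12 largest rises and 12 largest falls among genes past the threshold, moved alike in all 12 clones and with a group mean of at least 10 TPM. From each list it took up to 4 members past the threshold, or the 2 of highest expression. It also took the 15 most variable genes of at least 10 TPM and, on each called arm or block, the genes of the breast cancer lists and the 2 of highest expression. CCNE2, CDKN1A, EMILIN2, CD37 and genes named for a single library in the closing section were chosen after their values were seen. The alternatives fixed beforehand were other pseudocounts, filters, scalings, variance models, thresholds, references and block sizes, and leaving out each clone. Removal of a trend with GC content, the counts without AdE25, the spread of list scores without each clone, the estimated correlation in settings other than the main one, and the comparison of each library in turn with the other 12 were added after the data were seen. Some results for genes and blocks that the rule takes are not reported here.

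The model was tested on simulated data with 200 of 14893 genes changed in clones against the parental library, in 5 draws. It recovered 28.8% of genes changed by 1 on the log2 scale, 70.8% at 1.5, 81.6% at 2 and 96% at 3, with 5.7% false among called genes. The changed genes were drawn from those above about 10 TPM in the clones, with noise independent between genes. No gene called between the clones and the parental library reached 10 TPM, so these shares do not describe the range of the calls. The arm rule, tested on 10304 genes, called 100% of arms set at 0.5-fold, 97.2% at 0.75-fold, 63.9% at 1.25-fold and 100% at 1.5-fold, and 0% of 1332 unchanged arms. Arms set at 0.5-fold came out at a median log2 shift of -0.92.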

Results

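The data comprised 13 RNA sequencing libraries of HME-1, a non-transformed human mammary epithelial cell line, in its HME1-E6 form, which expresses the E6 protein of human papillomavirus. In 12 libraries the RNA came from clones that had survived transient overexpression of cyclin E, the G1/S cyclin that activates CDK2. These clones are named here as in the labels, from AdE1 to AdE45. The remaining library, named HME1-E6, had no replicate and was taken to be the untransduced parental line from its title and characteristics. The labels attach the cyclin E transduction protocol to this library too, so every comparison with it below, that of CCNE1 included, rests on that reading. Expression was given in TPM (transcript abundance scaled to the same total in every library), a unit that keeps no sequencing depth, so the depth of each library was unknown and no counting interval could be given. The series title asks whether the copy-number alterations that accompany cyclin E overexpression carry over into transcript levels. No copy-number measurements were analysed here, and the comparisons below concern RNA alone.

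CCNE1, which encodes cyclin E1, was not higher in the clones than in the parental library. It measured 9.07 TPM in the parental library and 8.15 ± 1.85 TPM in the clones (SD, n = 12), from 5.89 TPM in AdE44 to 11.2 TPM in AdE7. The log2 difference of -0.16 (SE 0.301) did not pass the threshold in limma's moderated test (adjusted p = 1.00), and 4 of 12 clones were higher than the parental library. CCNE2, which encodes cyclin E2, measured 8.72 TPM in the parental library and 10.96 ± 3.52 TPM in the clones. CDKN1A, the p21 inhibitor of CDK2, measured 65.1 TPM and 65.5 ± 16.8 TPM. The level of CCNE1 RNA measured here is that of surviving clones, and no library from the time of overexpression was analysed here.

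The first comparison asked which genes differed between the clones as a group and the parental line. EMILIN2, which encodes an extracellular matrix glycoprotein and lies on 18p, was lower in all 12 clones, at 0.059 ± 0.067 TPM (SD, n = 12) against 4.58 TPM in the parental library (log2 difference -2.40, SE 0.229, limma adjusted p = 8.42e-05). CD37, which encodes a leukocyte tetraspanin and lies on 19q, was also lower in all 12 clones, at 1.23 ± 0.435 TPM against 6.41 TPM (log2 difference -1.76, SE 0.317, limma adjusted p = 0.0367). Of the 14893 genes tested, 31 passed the threshold, 1 higher and 30 lower in the clones. Only 3 of these 31 were protein-coding, 24 were listed at 0 in all 12 clones, and the highest group mean among them was 6.41 TPM. No gene past the threshold reached the 10 TPM set for naming, so EMILIN2 and CD37 were named after their values were seen. The third protein-coding gene carries a clone-based name. Many of the genes at 0 in all clones were small RNA genes or pseudogenes, several of them at the same parental value of 3.591 TPM. Such a gene has no spread among the clones, so its call rests on the parental library alone. Its entry into the test does too, because the filter weights the parental library as much as all clones together. A total of 246 genes had an unadjusted p under 0.05, where 745 would be expected if no gene differed. With a stricter filter at 5 TPM, limma called 0 genes and 38 had an unadjusted p under 0.05. The call for CD37 was lost in 14 of 22 alternative settings, among them the fits without AdE7, AdE10, AdE17, AdE25, AdE27, AdE32, AdE37 or AdE45, where the log2 difference lay between -1.77 and -1.73.

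The parental library lay outside the range of all 12 clones for 971 of the 14893 genes, being above every clone for 735 and below every clone for 236. This was 6.52% of genes, where 15.4% would be expected of any library by chance. AdE25 lay outside the range of the other 12 libraries for 26.03% of genes and AdE44 for 7.76%. The filter weights the parental library as much as all clones together, so it favours genes that are high in that library. How far this shaped the split into genes above and below every clone was not tested. The libraries are therefore not on an equal footing in these shares.

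Gene groups were then compared between the clones and the parental library. Cell cycle genes ranked higher in the clones as a group at a preset correlation between genes, a call lost with an estimated correlation (adjusted p = 0.952). PCNA, the replicative sliding clamp, measured 201 ± 61.3 TPM in the clones (SD, n = 12) against 153 TPM in the parental library and was higher in 10 of 12 clones. RRM2, a subunit of ribonucleotide reductase, measured 161 ± 67.8 TPM against 111 TPM. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, measured 302 ± 122 TPM against 193 TPM, while the checkpoint protein gene BUB3 measured 295 ± 68.7 TPM against 314 TPM. The median log2 difference was 0.43 over 35 G2/M and mitosis genes (camera adjusted p = 6.28e-07) and 0.30 over 38 E2F and S-phase genes (camera adjusted p = 5.39e-06); with an estimated correlation each had an adjusted p = 0.952. The clones did not move alike, and the G2/M score was lower in AdE37 (-1.25) and AdE27 (-1.08) than in the parental library (-0.40). Ribosomal protein genes had a median of 0.24 over 55 members (camera adjusted p = 5.5e-17, adjusted p = 0.952 with an estimated correlation), with RPS27 at 8714 ± 809 TPM against 8011 TPM and RPL10 at 5509 ± 539 TPM against 5273 TPM. Hypoxia and glycolysis genes had a median of 0.22 over 27 members (camera adjusted p = 0.00124, adjusted p = 0.952 with an estimated correlation), with the glycolytic enzyme genes GAPDH at 3314 ± 706 TPM against 2831 TPM and ENO1 at 2407 ± 321 TPM against 2079 TPM, the latter higher in 11 of 12 clones. Oxidative phosphorylation genes had a median of 0.02 over 37 members (camera adjusted p = 0.0147, adjusted p = 0.952 with an estimated correlation), with COX8A at 1101 ± 109 TPM against 1069 TPM and COX6A1 at 653 ± 33.8 TPM against 658 TPM. Replication stress and DNA damage response genes had a median of 0.09 over 36 members (camera adjusted p = 0.0386, adjusted p = 0.952 with an estimated correlation), with the checkpoint kinase genes WEE1 at 46.9 ± 8.70 TPM against 43.6 TPM and CHEK1 at 45.1 ± 12.4 TPM against 43.3 TPM.

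These 6 of the 24 lists tested passed the threshold at the preset correlation of 0.01, all of them upward. None passed with an estimated correlation, where each had an adjusted p = 0.952. No member of any of the 24 lists passed the threshold in limma, whether adjusted over all genes or adjusted over the list alone (0 genes each way). The call for the replication stress list was lost in the fits without AdE1, AdE7, AdE10, AdE13, AdE32, AdE33 or AdE45, with adjusted p from 0.0508 to 0.0824, and kept in the other 5. Each of the 12 clones, when set against the other 12 libraries in the same way, gave between 2 and 10 lists past the threshold at the preset correlation, a comparison added after the data were seen.

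The other 18 lists did not pass the threshold. Among the epithelial and stromal markers, the basal keratin gene KRT17 measured 5078 TPM in the parental library and 2479 ± 1810 TPM in the clones (SD, n = 12), and the simple-epithelial keratin gene KRT7 measured 2041 TPM and 1451 ± 679 TPM. The median log2 difference was -0.40 for basal epithelial genes (camera adjusted p = 0.134), -0.29 for luminal epithelial genes (0.749), 0.40 for keratinocyte differentiation genes (0.749), -0.17 for mesenchymal genes (0.848) and -0.45 for fibroblast markers (0.166). At the preset correlation the basal list passed without AdE37 (camera adjusted p = 0.0454, adjusted p = 0.787 with an estimated correlation), as did the NF-kB and secretory cytokine list (camera adjusted p = 0.0448, adjusted p = 0.787 with an estimated correlation). The histone list passed without AdE37 (camera adjusted p = 0.0448, adjusted p = 0.743 with an estimated correlation) and without AdE17 (camera adjusted p = 0.0323, adjusted p = 0.956 with an estimated correlation). With the GC trend removed, the basal list (camera adjusted p = 0.0228), the fibroblast list (0.0479) and the proteasome list (0.0301) passed at the preset correlation as well. With an estimated correlation these had an adjusted p = 0.801, 0.801 and 0.836. Over all 12 clones the median of the cytokine list was -0.01 (camera adjusted p = 0.503), and CXCL1, a neutrophil chemokine gene of that list, measured 1189 TPM and 1363 ± 668 TPM. GADD45A, a p53-regulated stress gene, measured 755 TPM and 559 ± 149 TPM and was lower in 11 of 12 clones, whereas the apoptosis gene BAX measured 103.8 TPM and 103.6 ± 15.7 TPM. The median over p53 targets was -0.04 (camera adjusted p = 0.96). Medians were -0.16 for interferon response genes (0.749), -0.06 for heat shock genes (0.749), -0.06 for the unfolded protein response (0.795), 0.02 for the proteasome (0.266), -0.04 for mitochondrially encoded genes (0.964) and -0.18 for cholesterol synthesis (0.222), each with its camera adjusted p in parentheses. They were 0.05 for the cyclin E and CDK2 module (0.44), 0.20 for replication-dependent histones (0.0754) and -0.34 for genes at common fragile sites (0.643). Genes often gained in breast cancer had a median of -0.15 (0.96) and those often lost a median of -0.21 (0.643). YWHAZ, on 8q, measured 658 TPM and 528 ± 92.0 TPM. CCND1, the cyclin D1 gene on 11q, measured 223 TPM and 244 ± 75.4 TPM, and CDKN2A, on 9p, measured 154 TPM and 166 ± 22.7 TPM. For the heat shock, interferon, mitochondrial, p53 and unfolded protein response lists the median and mean were negative while camera's direction, taken relative to all other genes (median -0.08), was upward; the cytokine list had a negative median, a positive mean and an upward direction. Endothelial and immune markers had 3 and 1 measured members, too few to test.

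**Figure D1:**
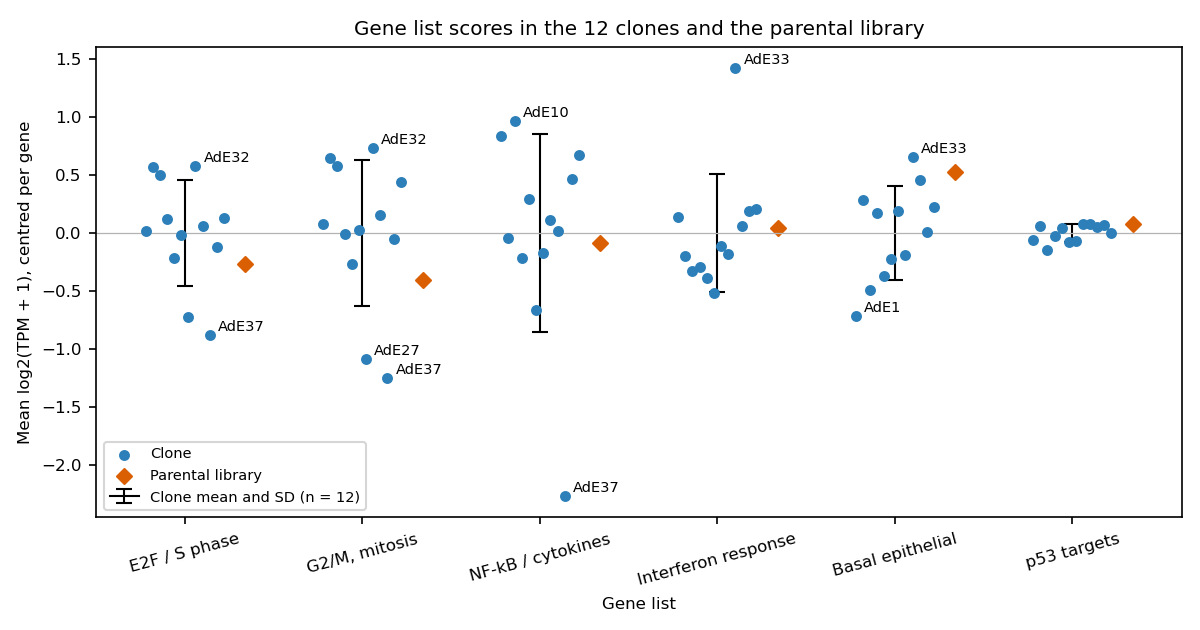
Gene list scores per library, as the mean over members of log2(TPM + 1) centred on the clone mean of each gene. Points are the 12 clones with their mean and SD, the diamond is the parental library, and the SD of the NF-kB and secretory cytokine list is 0.856 with AdE37 and 0.495 without it.

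Whole chromosome arms were then compared between each clone and the parental library, as shifts of RNA that were set against no copy-number values. The largest shift was that of 7p in AdE17, where the median gene was 1.93-fold higher (log2 0.95) and 94.3% of 174 genes were higher, against -0.07 ± 0.10 in the other clones (log2, SD, n = 11). PPIA, the cyclophilin A gene on 7p, measured 10781 TPM in AdE17 against 4995 TPM in the parental library and 4902 ± 849 TPM in the other clones. ACTB, the beta-actin gene, measured 11629.5 TPM against 8858 TPM and 7137 ± 1899 TPM, while the growth factor receptor gene EGFR, also on 7p, measured 43.2 TPM against 41.8 TPM. The arm 18p in AdE27 was 1.82-fold higher (log2 0.86), with 97.6% of 42 genes higher, against -0.03 ± 0.20 in the other clones. The neighbouring myosin light chain genes MYL12A and MYL12B on 18p measured 1759 TPM and 1469.6 TPM in AdE27 against 923 TPM and 838 TPM in the parental library, and they are near-identical copies whose split is uncertain. The most negative shift was that of Xq in AdE45, at 0.719-fold (log2 -0.48), with 78.4% of 194 genes lower.

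In all, 26 of 492 arm shifts (41 arms in each of 12 clones, 10304 genes) reached 0.3 on the log2 scale and lay outside all 10000 random gene lists of matched expression. Of these 10 were higher and 16 lower; without centring on the genome-wide median the split was 7 higher and 28 lower. Against the parental library each of the 12 clones had at least 1 such arm; against the median of the other clones AdE44 had 0. Shifts that did not reach this rule had an SD of 0.102, and 73.6% of them lay within 0.1 of 0. The parental library, set against the median of the clones by the same rule, had 0 such arms, with shifts from -0.15 to 0.12. Each clone had 1 library, so no arm shift has a replicate check and no p-value was computed.

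Other arms higher in a clone were 17p in AdE1 (log2 0.45) and AdE13 (0.40), 4q (0.43) and 4p (0.37) in AdE1, and 18p in AdE33 (0.36). RPL34 on 4q and RPL9 on 4p, both ribosomal protein genes, measured 4016 TPM and 1552 TPM in AdE1 against 1920.5 TPM and 559 TPM in the parental library. FAT1, a tumour suppressor gene on the same 4q, measured 18.7 TPM against 47.2 TPM. On 17p in AdE1, RPL26 measured 3491 TPM against 1767 TPM, and MAP2K4, a stress-kinase gene, 6.45 TPM against 12.7 TPM. Ribosomal protein genes were higher in AdE1 as a list, with a median log2 difference of 0.288 from the other 12 libraries over 55 members. RPL23, in a lower stretch of 17q in AdE1, also measured 3271 TPM against 2240 TPM. The values of RPL34, RPL9 and RPL26 therefore cannot be credited to their arms. In AdE13 94.8% of the 172 genes of 17p were higher, and in AdE33 95.2% of the 42 genes of 18p. In AdE25 the arms 19p (0.42), 19q (0.34) and 16p (0.31) were higher; CCNE1, on 19q, measured 11.01 TPM there. These 3 shifts fell short of the rule against the median of the other 11 clones (0.30, 0.22 and 0.27) and after the trend of AdE25 with GC content was removed (0.12, 0.13 and 0.06).

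Of the arms lower in a clone, 8p was so in AdE1 (log2 -0.34), AdE10 (-0.31) and AdE7 (-0.31). On 8p, LOXL2, a collagen-crosslinking oxidase gene, measured 306 TPM, 249.6 TPM and 487 TPM in these clones against 844 TPM in the parental library. FDFT1, the squalene synthase gene and the other of highest expression on 8p, measured 439 TPM, 512 TPM and 373 TPM against 386 TPM. FGFR1, a receptor kinase gene often amplified in breast cancer, measured 19.6 TPM, 14.1 TPM and 25.8 TPM against 34.1 TPM, whereas PPP2R2A, a phosphatase subunit gene, measured 28.7 TPM, 28.01 TPM and 23.4 TPM against 23.2 TPM. The arm 12p was lower in AdE17 (-0.40), with 87.2% of 133 genes lower, against -0.05 ± 0.11 in the other clones (SD, n = 11). The arm 9p was lower in AdE25 (-0.39), where MTAP, of the methionine salvage pathway, measured 15.9 TPM against 31.7 TPM in the parental library and 28.9 ± 4.11 TPM in the other clones. The cell cycle inhibitor gene CDKN2B measured 32.3 TPM against 67.3 TPM and 40.05 ± 13.9 TPM, and its neighbour CDKN2A 143 TPM against 154 TPM and 168 ± 22.6 TPM, so that both lay near the spread of the other clones. The arm 13q was lower in AdE32 (-0.36), with 83.9% of 168 genes lower, against 0.01 ± 0.05 in the other clones, and RB1 measured 21.9 TPM against 28.7 TPM in the parental library and 23.9 ± 5.80 TPM in the other clones. SMAD4, the transforming growth factor signal transducer on 18q, measured 35.1 TPM in AdE44 against 67.2 TPM in the parental library and 47.03 ± 10.97 TPM in the other clones, with 18q at -0.34. The arm 7p, higher in AdE17, was lower in AdE45 (-0.34), where PPIA measured 3070.0 TPM and ACTB 5755 TPM. Also lower were 5q (-0.36) and 18q (-0.30) in AdE17, Xq in AdE7 (-0.34), 18p in AdE13 (-0.33), 10p in AdE45 (-0.31), 7q in AdE33 (-0.32, with 91.2% of 307 genes lower) and 16q in AdE37 (-0.32, with 88.5% of 227 genes lower). MT2A, a metallothionein gene on 16q, measured 1988 TPM in AdE37 against 4727 TPM in the parental library and 4594 ± 954 TPM in the other clones.

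Single genes did not all follow their arm. Of the 61 values of genes taken by the naming rule on the lower arms, 49 were below the parental library and 12 above it. Among the latter were HMGB1 on 13q in AdE32 (327 TPM against 286 TPM) and RPS6 on 9p in AdE25 (1239.6 TPM against 1115 TPM). ATRX on Xq in AdE45 (49.1 TPM against 33.7 TPM) was also above it. It lies outside the lower stretch of that arm from CENPI to TMLHE, in a block that was higher in AdE45 (log2 0.21). On the higher arms 24 of 29 such values were above the parental library and 5 below it. The 26 shifts fell on 18 arms, of which 12 were found in 1 clone. Every clone was compared with the same parental library, whose own shift against the median of the clones was -0.02 for 8p, 0.12 for 18q, 0.06 for Xq and -0.09 for 17p. For 19p and 19q that shift was -0.12 and -0.15. Against the median of the other 11 clones 8p was again called in AdE1 (-0.37), AdE10 (-0.36) and AdE7 (-0.35). Against the median of the other 11 clones 26 arm shifts were again found, of which 18 were shared with those against the parental library; besides the 3 higher arms of AdE25, the shifts that no longer reached 0.3 were 16q in AdE37 (-0.2992), Xq in AdE7 (-0.27), 18q in AdE44 (-0.26) and AdE17 (-0.19), and 10p in AdE45 (-0.26). With the GC trend removed in each clone, 19 of the 26 were found again, and besides the 3 higher arms of AdE25 the shifts that no longer reached 0.3 were 8p in AdE10 (-0.2995) and AdE7 (-0.2989), 18p in AdE13 (-0.27) and 18q in AdE17 (-0.23).

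**Figure D2:**
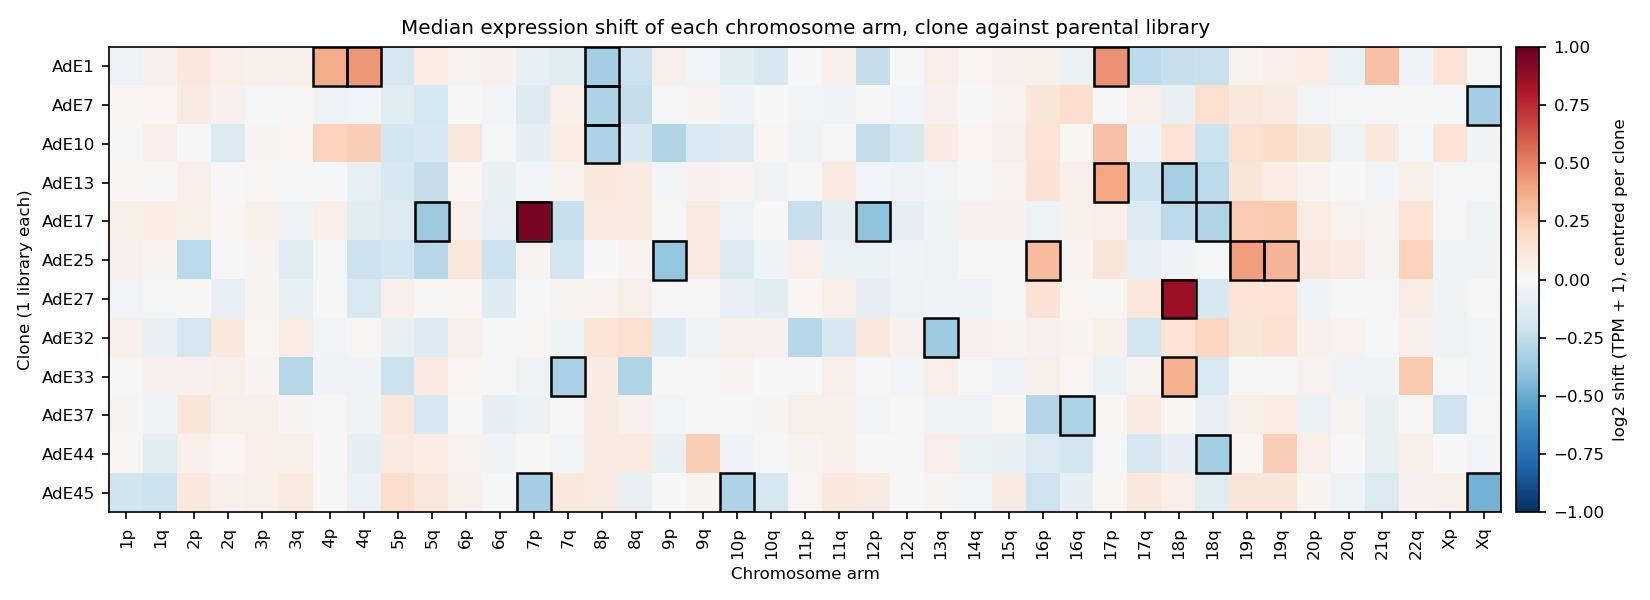
Shift of each chromosome arm in each clone, as the median over genes of log2(TPM + 1) in the clone minus the parental library, centred on the clone's genome-wide median. Boxed cells are the 26 shifts past the rule, from -0.48 for Xq in AdE45 to 0.95 for 7p in AdE17.

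Shorter stretches were examined in blocks of 50 neighbouring genes. The genes from C11orf70 to ACAD8 on 11q were lower in AdE7, at 0.647-fold (log2 -0.63), with 90.3% of 124 genes lower, although 11q as a whole did not pass the rule in that clone. TAGLN, the smooth-muscle transgelin gene in this stretch, measured 729 TPM against 3626 TPM in the parental library and 2294 ± 1443 TPM in the other clones (SD, n = 11), and the chaperone gene HSPA8 1056 TPM against 1190.0 TPM. On 5q in AdE17 the 169 genes from CXXC5 to TRIM52-AS1 were at 0.722-fold (log2 -0.47), with SPARC, a secreted matrix protein gene, at 2134 TPM against 4118 TPM in the parental library and 2979.8 ± 1031 TPM in the other clones. On Xq the genes from CENPI to TMLHE were at 0.663-fold in AdE45 (log2 -0.59), and those from CENPI to CD99L2 at 0.740-fold in AdE7 (log2 -0.43). AdE1 and AdE10 shared blocks on Xp. The block from ARSD to PDK3 on Xp was lower in both (log2 -0.50 and -0.42), and that from PCSK1N to ZXDB, also on Xp, was higher in both (0.56 and 0.57). On 17p the genes from RNF167 to MAP2K3 were higher in AdE1 (0.54). TMSB4X, a thymosin gene that lies in the lower Xp block, measured 4755 TPM in AdE1 and 3975 TPM in AdE10 against 9750.0 TPM in the parental library.

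Of 2484 block shifts (207 per clone), 53 reached 0.4 and lay outside all 10000 random lists, 24 higher and 29 lower. They formed 39 stretches in 10 clones, of which 18 lay on arms that did not pass the arm rule. Against the median of the other 11 clones 41 block shifts were found, of which 29 were shared with the 53. AdE25 held 17 of the 53, and 2 once the GC trend was removed; 36 were found without AdE25. A total of 31 blocks were found in 1 clone and 11 in 2 clones.

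**Figure D3:**
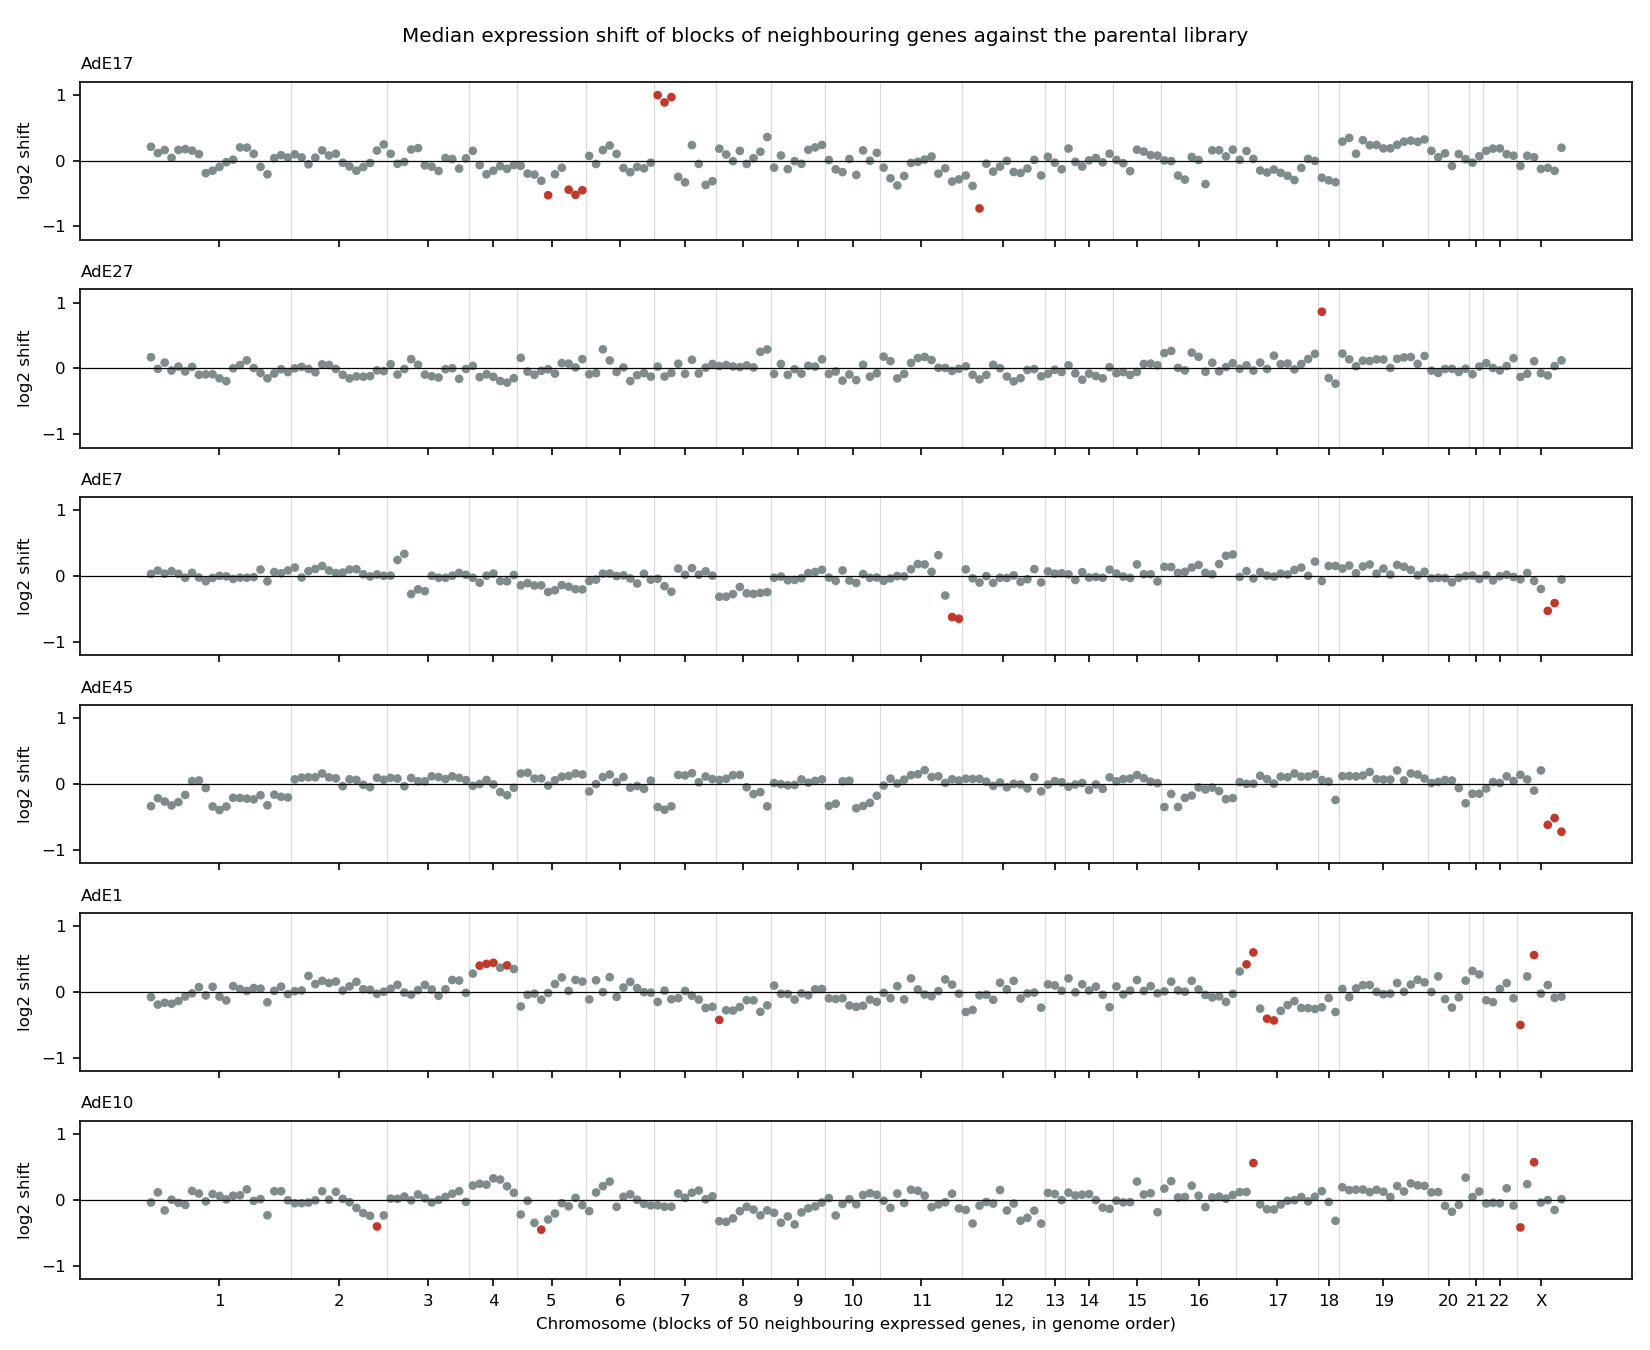
Shift of each block of 50 neighbouring genes along the genome in AdE17, AdE27, AdE7, AdE45, AdE1 and AdE10, as log2 clone minus parental library centred on the genome-wide median. Blocks past the rule are red, among them all 3 blocks of 7p in AdE17.

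Variation among the 12 clones was described gene by gene. IGFBP5, an insulin-like growth factor binding protein gene, ranged from 2.71 TPM in AdE10 to 1453 TPM in AdE37 (SD 2.77 on the log2 scale, n = 12), with 520 TPM in the parental library. IGFBP2, of the same family, ranged from 0.584 TPM in AdE10 to 133 TPM in AdE37, and the oxytocin receptor gene OXTR from 3.15 TPM in AdE1 to 553 TPM in AdE37. Among secreted signals, the chemokine gene CXCL12 ranged from 0.281 TPM in AdE33 to 91.4 TPM in AdE32, CCL2 from a listed 0 in AdE37 to 116 TPM in AdE13, and CSF3, the granulocyte colony-stimulating factor gene, from 1.64 TPM in AdE37 to 426 TPM in AdE10. The adhesion genes CADM1 and EDIL3 were lowest in AdE1 (0.68 TPM) and AdE17 (0.498 TPM) and highest in AdE33 (256 TPM) and AdE44 (217 TPM). S100A8, a calcium-binding alarmin gene, reached 227 TPM in AdE1, GSTA1, a glutathione transferase gene, 118 TPM in AdE27, and GFRA1, a co-receptor gene, 28.6 TPM in AdE25. The other 4 of the 15 most variable genes were RNU6-33P, RNU6-36P, RN7SL33P and Z82188.1, each listed at 0 in the parental library and in at least 3 clones; the first 3 are copies of small RNA genes whose TPM values are uncertain. Of the 8092 genes ranked, the median SD was 0.275 and 100 genes had an SD above 1.

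By gene list, the NF-kB and secretory cytokine score ran from -2.27 in AdE37 to 0.97 in AdE10, with an SD of 0.856 over 12 clones and 0.495 without AdE37. The keratinocyte differentiation score, over only 6 members, had an SD of 0.714, where random lists of that size had a median SD of 0.211. The G2/M score, over 35 members, had an SD of 0.627 (AdE37 lowest at -1.25, AdE32 highest at 0.73), where that median was 0.088. The interferon score had an SD of 0.506 (AdE33 highest at 1.42), or 0.248 without AdE33. Set among 1000 random lists of the same size, the SDs of these 4 lists lay at percentile 100.0. So did those of the E2F, mesenchymal, basal, cholesterol, hypoxia, replication stress and ribosomal protein lists. Members of a random list need not vary together, so a list whose members do will tend to exceed them, and the percentile does not single out these 4. The p53 target score had an SD of 0.076, at percentile 4.7, where the median SD of the random lists was 0.111. All 13 libraries are of HME1-E6 cells, so p53 target values of cells without E6 were not available to set beside it. These percentiles describe the 12 clones, and no test between groups of clones was made, since the labels divide the clones into no subgroups.

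Finally, the SD over arms of each clone's shifts against the other clones was compared with 9 list scores across the 12 clones. Heat shock genes had the largest correlation in size (Pearson r = -0.452, permutation p = 0.142, Benjamini-Hochberg p = 0.877; Spearman rho = -0.490, permutation p = 0.110, Benjamini-Hochberg p = 0.558; two-sided, n = 12), with r = -0.463 without AdE1 and AdE17, the clones farthest from the median imbalance. The cytokine list gave r = 0.378 (permutation p = 0.216, Benjamini-Hochberg p = 0.877) and rho = 0.413 (permutation p = 0.186, Benjamini-Hochberg p = 0.558), with r = 0.321 without those clones. For p53 targets r was -0.235 (permutation p = 0.465, Benjamini-Hochberg p = 0.877) and rho -0.462 (permutation p = 0.135, Benjamini-Hochberg p = 0.558), with r = -0.496 without those clones. None of the 9 relations had a Benjamini-Hochberg p under 0.05, and 0 had an unadjusted permutation p under 0.05. The labels name no sequencing or library batch, so no within-batch values could be given.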

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

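The removal of the GC trend, the counts without AdE25, the list spreads without each clone, the estimated correlation in settings other than the main one and the tests built on them were chosen only after the results were seen. No paired analysis was possible because the parental line has 1 library and the labels do not pair it with any clone. The 31 genes between clones and parental library became 47 with a pseudocount of 5, 455 with no filter on low values, 0 with a filter at 5 TPM (38 at an unadjusted p under 0.05 in limma), 63 without mitochondrial and ribosomal protein genes, and 17 with the GC trend removed. They ranged from 29 to 35 without each clone in turn. The filters change which low genes enter; the cause of the other changes was not tested. EMILIN2 stayed lower and past the threshold in all 22 alternatives that tested it, whereas CD37 stayed lower but lost its call in 14 of 22. CCNE1 kept a negative difference short of the threshold in 23 alternatives, from -0.20 to -0.09. The 6 gene lists became 0 with an estimated correlation, which by its construction allows for members that vary together; with it 0 also passed without each clone in turn, after rescaling and with the GC trend removed. With the GC trend removed 9 lists passed, the basal, fibroblast and proteasome lists being gained. The share of genes for which the parental library lay outside all clones was 5.06% with a filter at 5 TPM. Arm shifts numbered 61 at a threshold of 0.2 and 7 at 0.4. The sign was kept for all 26 in every setting in which the arm was measured, and 6 were called in each of them: 4q and 17p in AdE1, 7p and 12p in AdE17, 18p in AdE27 and Xq in AdE45. A total of 15 were called against both references and with the GC trend removed. Block shifts numbered 41 against the median of the other clones (29 shared), 30 with the GC trend removed (the cause was not tested beyond AdE25, which went from 17 to 2), 142 at a threshold of 0.3 and 16 in blocks of 100 genes, of which there are fewer. No relation of arm imbalance with a list score passed adjustment under any setting; the smallest unadjusted p was 0.0428, for Spearman's rho of p53 targets against imbalance from the parental reference (Benjamini-Hochberg p = 0.385). Among single genes, lists and arms, 648 alternative values kept their side of the threshold or stayed within 1.5 times, 76 lost their call, 7 gained one, 3 changed by more than 1.5 times and 0 reversed. Among the main counts and shares 45 alternative values stayed within 1.5 times and 26 moved further or, for the share of genes, left its binomial interval. Of the 6 list spreads reported, those of the cytokine list (0.495 without AdE37), the interferon list (0.248 without AdE33) and the cholesterol list (0.178 without AdE45) changed by more than 1.5 times. The unknown depth limits what can be said of genes listed at 0, and the lone parental library limits every comparison with it.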

Other observations

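The comparison of each library with the other 12, and the tests below on GC content, on the parental reference and on other lone libraries, were chosen only after the results were seen; so were the allowances made for other arms and other pairs of clones. Adjusted over all 312 tests of a list in a library, 0 held with an estimated correlation (smallest adjusted p = 0.101; 71 passed at the preset correlation in camera), so the list values here are descriptions. Adjusted within each library, 3 passed with an estimated correlation: the interferon list in AdE33 (adjusted p = 0.00774), the cytokine list in AdE37 (0.0158) and the cholesterol list in AdE45 (0.0335). In AdE37 the median log2 difference from the other 12 libraries was -2.37 over the 26 members of the NF-kB and secretory cytokine list (adjusted p = 0.103 over all tests with an estimated correlation), -1.36 for the G2/M list and -0.96 for the E2F list (adjusted p = 0.954 each with an estimated correlation). Adjusted p-values of single genes below are from limma over all genes and all 13 libraries together. CXCL1, a neutrophil chemokine gene, measured 35.9 TPM against 1459 ± 528 TPM (SD, n = 12; log2 -5.23, SE 0.465, limma adjusted p = 0.000286). CSF2, the GM-CSF gene, measured 3.47 TPM against 155 ± 56.7 TPM, the complement gene C3 11.4 TPM against 276 ± 94.97 TPM, and the interleukin 8 gene IL8 47.8 TPM against 1422 ± 620 TPM (limma adjusted p = 0.0056). TNFAIP3 and ZC3H12A, which encode feedback regulators of this pathway, measured 7.19 TPM and 11.7 TPM against 53.3 ± 16.1 TPM and 49.7 ± 9.68 TPM (limma adjusted p = 0.0548 and 0.0129). In AdE33 the median over the 23 members of the interferon list was 1.52 (adjusted p = 0.101 over all tests with an estimated correlation), with IFIT3 and MX1 at 32.2 TPM against 6.99 ± 1.43 TPM (log2 2.08, limma adjusted p = 0.0183) and 22.3 TPM against 2.01 ± 1.11 TPM (log2 3.02, limma adjusted p = 0.0295). In AdE45 the median over the 24 members of the cholesterol synthesis list was -0.83 (adjusted p = 0.145 over all tests with an estimated correlation), and the SD of that list's score over the clones was 0.295 with AdE45 and 0.178 without it. DNAJC15, a mitochondrial co-chaperone gene on 13q, measured 0.529 TPM in AdE32 against 11.4 ± 1.62 TPM (log2 -3.01, limma adjusted p = 0.000132). In AdE13 THOC2, an mRNA export gene, measured 152 TPM against 29.5 ± 5.83 TPM (log2 2.35, limma adjusted p = 0.00379). In these fits the lone library has no replicate and is assumed to vary like the others.

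In AdE17, 38 genes passed the threshold in limma against the other 12 libraries when adjusted within that fit, and 31 of the 36 higher ones lie on 7p, which holds 231 of the 14893 genes tested. Adjusted over all 13 libraries together, 9 passed, 6 of them on 7p. PSMA2, a proteasome subunit gene, measured 429.7 TPM against 177 ± 26.3 TPM (SD, n = 12; log2 1.29, limma adjusted p = 0.117 over all libraries), and POLD2, a DNA polymerase delta subunit gene, 437 TPM against 209 ± 24.9 TPM (0.122). EDIL3, on 5q, measured 0.498 TPM against 112 ± 55.9 TPM (log2 -6.07, limma adjusted p = 0.0022 over all libraries). Basal markers differed widely in level in the parental library, with KRT17 at 5078 TPM and ITGA3 at 691 TPM. KRT5 measured 0.639 TPM in the parental library and at most 0.509 TPM in a clone, and TP63 0.065 TPM and at most 0.212 TPM, whereas VIM measured 4975 TPM and 4940 ± 647 TPM. KRT14 ranged from 0.193 TPM in AdE32 to 17.5 TPM in AdE7, against 16.5 TPM in the parental library. TERT, the telomerase catalytic subunit gene, ranged from 0.651 TPM in AdE25 to 13.6 TPM in AdE1, against 0.665 TPM. KRT5, TP63, KRT14 and TERT were named after their values were seen and were not tested further here.

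The higher values of 19p, 19q and 16p in AdE25 could come from a trend with GC content or from more copies of these arms. These arms are GC-rich (median 60.8%, 58.9% and 58.2% against 49.6% over all genes), and AdE25 had the strongest correlation over genes between log2 ratio and GC content (r = 0.393, across genes, which are not independent). With the GC trend of the other arms removed, the median of the 3 shifts fell to 0.1617, between the bounds set for either reading. The 125 genes of these arms with GC content below the median had a median shift of -0.1113 (bootstrap interval -0.201 to -0.0461), which met the bound set beforehand against more copies. That bound was wrong, since low-GC genes of other arms lay lower still in AdE25, at -0.19, a difference of 0.0825, so the 2 explanations cannot be told apart here. The reference also bears on 19p and 19q, where the parental library lay at -0.12 and -0.15 against the median of the clones. Against that library the other 11 clones lay at 0.10 ± 0.07 on 19p and 0.13 ± 0.08 on 19q (log2, SD).

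AdE1 and AdE10 had the highest correlation of block shifts of the 66 pairs of clones, although AdE17 and AdE25 had a higher block covariance before the GC trend was removed (0.0214 against 0.0177). GC content did not account for it: the correlation of their block shifts was 0.636 before and 0.6349 after the GC trend was removed, although AdE25 and AdE32 then came close at 0.614. An expression programme with no link to gene position is also argued against as the whole cause, because the block covariance with the GC trend removed, 0.0161, lay above the highest of 1000 joint shuffles of genes over positions (0.00354). Position alone is common, since 36 of the other 65 pairs also lay above all of their shuffles, of which each pair had only 100. Over all 65 other pairs the median covariance was 0.00104 and the highest 0.00954. A shared origin of the clones or mixed cultures may be considered as a hypothesis and was not tested, and both clones also had the highest ribosomal protein share of TPM (21.2% each).

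The 16 lower arm shifts had a median of -0.336, a 0.792-fold level, which is smaller than an arm at 0.5-fold would give. Chance values of the parental library are argued against, because the median was -0.349 against the other 11 clones, with a range from -0.438 to -0.194. A change limited to part of the arm is argued against only for the more even arms (7q in AdE33 with blocks from -0.34 to -0.28, 16q in AdE37 from -0.33 to -0.25). Of the 15 lower arms with 2 or more blocks, 2 had a block above -0.1, both of them Xq. The arm rule asks for a low median over the whole arm, so arms changed only in part were less likely to be called. That count therefore cannot decide the question, and 18 of the 39 stretches lay on arms that did not pass the rule. A change in part of the arm stays open for Xq and for uneven arms such as 5q (-0.53 to -0.11) and 12p (-0.73 to -0.23) in AdE17, 18q in AdE44 (-0.49 to -0.15) and 9p in AdE25 (-0.60 to -0.21). Loss of a copy from cells that hold more than a pair, or in part of a culture, could also give such values and was not tested, nor was any biological explanation.

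The 31 genes between the clones and the parental library were set against the same fit with each library in turn as the lone one. Of these 13 splits, 2 gave as many genes or more, the real one and that with AdE17 alone, which gave 38. With 13 splits the share cannot go under 0.077, so the splits are too few for a share under 0.05. The splits are also not alike, because all used the genes kept by the filter on the mean of the clone mean and the parental value. That filter weights the parental library as much as all clones together. A low gene seen in the parental library alone therefore enters more easily than a gene seen in a single clone alone. The called genes listed at 0 in all clones entered through the parental value alone, so these splits cannot decide the question. AdE1, AdE10, AdE44 and AdE45 each gave 0 genes in limma, with 1412, 1390, 244 and 718 genes at an unadjusted p under 0.05.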
